A study of Homo sapiens with 6 samples.

How the data were processed

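RNA from MDA-MB-231 cells treated for 48 h with 50 µM TCI04 or with PBS was measured on Affymetrix arrays, with 3 arrays per group, per the labels. The deposited values are intensity values on a linear scale, 1 per probe set and array. The submitters' processing notes name MAS5, which computes a signal per probe set within each array. In the deposited table, the mean without the lowest and highest 2% of values was 500.1 on every array, so the authors' intensity values had been scaled per array. The software version and detection calls were not given in the sources used here.

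The table held 54675 probe sets, of which 62 were controls; the result of 1 control probe set is not reported here. Platform annotation gave 1 gene symbol for 41097 probe sets, several for 1801 and none for 11777, and only probe sets with 1 symbol were named. The Entrez ID of 41043 of these matched the RefSeq gene table, and 0 symbols changed. No coordinates were used, because no genome build is named for the array.

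Signals were converted to log2(signal + 10.96), the offset being the 20th percentile of all values. Fold changes are on this scale, which understates the change of dim probe sets. Control probe sets and probe sets whose mean lay below the 40th percentile (a signal of about 33.9) were left out, which left 32746. A linear model was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend, two-sided, TCI04 minus PBS), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Each of 13679 genes was represented by its probe set with the highest mean. Intervals of 95% used the moderated total of 10.5 degrees of freedom. Gene lists (37 fixed before the data were examined, 35 with at least 5 measured members) were tested with camera at an inter-gene correlation of 0.01. Ratios of 3' to 5' control probe sets were compared by exact permutation tests.

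The rule for named genes was fixed before the data were examined. It took genes past the adjusted threshold with non-overlapping groups, up to 12 in each direction; up to 4 passing members of each list; ACTB and GAPDH; and, where fewer than 5 genes passed in a direction, the 5 with the smallest p in it. A list could be given with up to 2 examples, its members with the highest level. Which lists received examples was settled after the results were seen: those with an unadjusted camera p under 0.05 and the list holding FOS. Genes named outside the rule are said to have been chosen after their values were seen.

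The steps were tested on simulated data with 200 of 32746 probe sets changed in a comparison of 3 against 3 arrays. The fit recovered 41% of those changed 1.5-fold, 61% of those changed 2-fold and 92.6% of those changed 4-fold, with 10.1 unchanged probe sets called per simulation. The simulated noise was independent between probe sets. With 200 changed probe sets, the adjusted threshold is also easier to reach than in data where few are called. These shares therefore check the steps and are not the power of the real comparison.

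Alternatives were quantile normalization, median centring, an offset of 1 or of the table median of 63.6, no filter or a filter at the 60th percentile, the mean of a gene's probe sets, leaving out probe sets prone to cross-hybridization, eBayes without trend or with robust settings, array weights, the replicate number as a block, each array left out, an ordinary t-test, camera with an estimated correlation, and fry. To place a list among genes of like level, its median was set against 10000 random lists matched on mean level in 20 bins. After those values had been seen, matching to the 100 genes nearest in mean level was added, because the brightest bin spans a wide range of signal.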

Results

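Gene expression was measured in MDA-MB-231 cells, a human triple-negative breast cancer cell line, after 48 h with 50 µM TCI04, a compound known here only by its code name, or with phosphate-buffered saline (PBS) as the vehicle. Each group held 3 arrays. The values were MAS5 signals, a summary of the probes of each probe set on a linear scale, and all 6 arrays had the same trimmed mean signal of 500.1. The median signal was 64.0 to 74.3 in the PBS arrays and 58.9 to 59.8 in the TCI04 arrays. Spearman correlations across probe sets were 0.932 to 0.938 within groups and 0.931 to 0.940 between groups. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

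The comparison asked which transcripts differed between cells given TCI04 and cells given PBS. FOS, which encodes a subunit of the AP-1 transcription factor and is an immediate-early gene, fell with TCI04. Its signal (from the only probe set for the gene) was 1151 ± 56.8 with PBS and 512 ± 44.8 with TCI04 (SD, n = 3 arrays each), 2.23-fold lower. The log2 fold change was -1.16 with a standard error of 0.10 and a 95% interval from -1.37 to -0.94 (limma, adjusted p = 0.00611). All 3 TCI04 arrays, at 471, 506 and 560, lay below all 3 PBS arrays, at 1086, 1183 and 1186. FOS was the only one of 32746 tested probe sets past the adjusted threshold of 0.05, and no probe set passed it toward higher values.

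The next smallest adjusted p was 0.697 in limma. At an unadjusted p under 0.05, 723 probe sets had higher and 1597 lower means with TCI04. These were 2320 in all, against 1637 that chance would give on average. Regroupings of the arrays that mixed PBS and TCI04 gave from 997 to 2167 such probe sets. The count of 2167 came from setting PBS replicate 1 together with TCI04 replicates 1 and 3. The excess over 1637 is therefore not by itself evidence of a broad effect of TCI04. The balance of higher and lower means moved with the scaling of the arrays. It was 1002 higher and 1041 lower after quantile normalization, and 1426 higher and 996 lower with arrays centred on their medians. A test of each probe set on its own variance alone, with the same adjustment, called 0 probe sets, and 2055 at the unadjusted threshold. The FOS call was lost in that test (adjusted p = 0.491) and in limma without a variance trend (adjusted p = 0.462). It was also lost without PBS replicate 1, 2 or 3 (adjusted p = 0.0602, 0.117 and 0.125) and without TCI04 replicate 1 or 2 (adjusted p = 0.052 and 0.0518), while its log2 fold change stayed between -1.22 and -1.08 in all 19 alternatives.

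The other genes with the smallest p in each direction failed the correction, each with an adjusted p of 0.697 in limma. On the lower side they were NOC2L, GRK2, LMF1 and the non-coding RNA LINC03011. NOC2L, a nucleolar protein that binds histones, had a signal of 507 ± 25.0 with PBS and 303 ± 24.6 with TCI04, a log2 fold change of -0.73. The G protein-coupled receptor kinase GRK2 measured 440 ± 45.5 and 255 ± 42.9, a log2 fold change of -0.77. LMF1, a maturation factor for lipases, measured 306 ± 37.9 and 151 ± 42.5, 1.99-fold lower, although its other probe sets gave log2 fold changes of -0.19 and -0.28. LINC03011 had a log2 fold change of -0.83.

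On the higher side the 5 genes were ABHD3, PEX11A, N4BP2, ATF2 and TMEM131. The phospholipase ABHD3 had a signal of 1207 ± 12.7 with PBS and 1658 ± 136 with TCI04, a log2 fold change of 0.45. The peroxisomal membrane protein PEX11A measured 184 ± 22.4 and 318 ± 31.2, a log2 fold change of 0.76, and its other probe set gave 0.20. ATF2, a transcription factor that can pair with JUN, had a log2 fold change of 0.42, and its other probe set gave -0.14. N4BP2 had a log2 fold change of 0.49, which turned to -0.30 when its probe sets were averaged, since its dimmer probe set gave -1.09. TMEM131 had a log2 fold change of 0.32. For each of these 9 genes the 3 TCI04 arrays and the 3 PBS arrays did not overlap, as was the case for 1853 of 13679 genes (13.5%, where chance gives 10%).

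**Figure D1:**
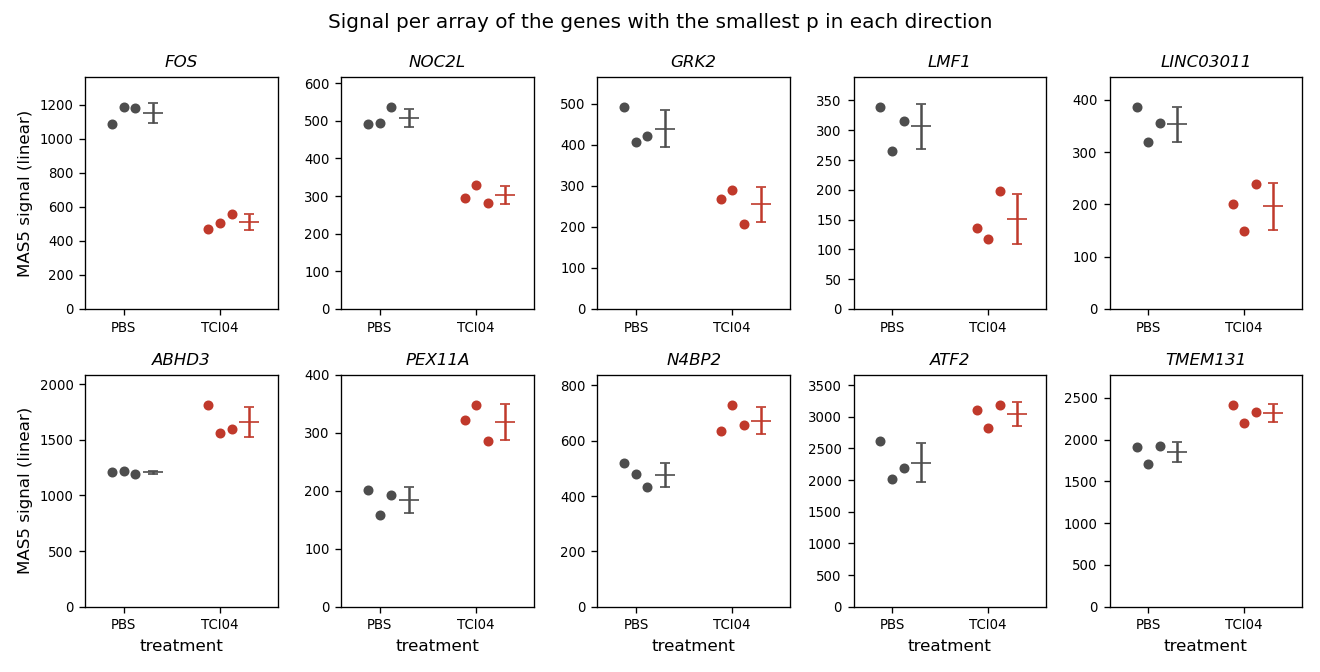
MAS5 signal (linear, axes from 0) of FOS and the other 9 genes with the smallest p, lower with TCI04 in the top row and higher in the bottom row. Points are arrays, and the bars beside them are the mean and SD of 3 arrays; FOS lay between 471 and 560 with TCI04 and between 1086 and 1186 with PBS, and the other 9 genes failed the correction.

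FOS was also the only member of the list of ERK pathway output that passed, both over all genes and adjusted over the list alone. Of its 23 measured members, 16 had a higher mean and 7, FOS included, a lower mean with TCI04. The members with the highest level, PHLDA1 and the ERK phosphatase DUSP6, had log2 fold changes of 0.02 and -0.09. The other probe sets gave -0.623 to 0.159 for PHLDA1 and 0.024 and 0.047 for DUSP6. As a list, ERK pathway output did not pass (limma camera, adjusted p = 0.656).

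Of 35 gene lists tested, 3 passed in camera, all toward lower values with TCI04 and each with an adjusted p of 0.0108. None of the 3 calls held with an estimated correlation between genes (adjusted p = 0.87 for each). In the list of ribosome biogenesis and MYC targets, 20 of 25 measured members had a lower mean, with a median log2 fold change of -0.10. Its members with the highest level, the nucleolar proteins NPM1 and DDX21, had log2 fold changes of -0.13 and -0.05, and of -0.015 and -0.017 after quantile normalization. DDX21 turned to 0.01 with median centring. The other probe sets gave -0.074 and -0.009 for NPM1 and -0.06 for DDX21. In the glycolysis list, 14 of 17 members had a lower mean, with a median of -0.07. GAPDH and LDHA, its members with the highest level, had log2 fold changes of -0.14 and -0.13, and of -0.035 and -0.021 after quantile normalization. The other probe sets of GAPDH gave -0.158 and -0.198. In the list of reference genes, which shares 2 members with the glycolysis list, 10 of 11 members had a lower mean, with a median of -0.06. Among these, ACTB measured 44970 ± 1655 with PBS and 38880 ± 2809 with TCI04, a log2 fold change of -0.21, and PPIA had a log2 fold change of -0.15. After quantile normalization these were -0.083 and -0.029. The other probe sets of ACTB gave -0.102 and -0.12. In none of the 3 lists did a member pass, over all genes or adjusted over the list alone.

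None of the 3 list calls held without PBS replicate 2, PBS replicate 3 or TCI04 replicate 3, with arrays centred on their medians (adjusted p = 0.294 to 0.452), without the filter on dim probe sets (0.0645 for each), without a variance trend (0.193 to 0.198) or without probe sets prone to cross-hybridization (0.16 to 0.94). Quantile normalization ended the calls of glycolysis (adjusted p = 0.137) and the reference genes (0.145), as did averaging the probe sets of a gene (0.262 and 0.444), and 6 lists passed without PBS replicate 1. The medians of the 3 lists in PBS replicate 1, relative to the mean of the PBS arrays, were -0.08 for glycolysis, -0.11 for the reference genes and -0.05 for ribosome biogenesis, within the ranges of the TCI04 arrays (-0.12 to -0.04, -0.10 to -0.07 and -0.08 to -0.04) or below them.

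**Figure D2:**
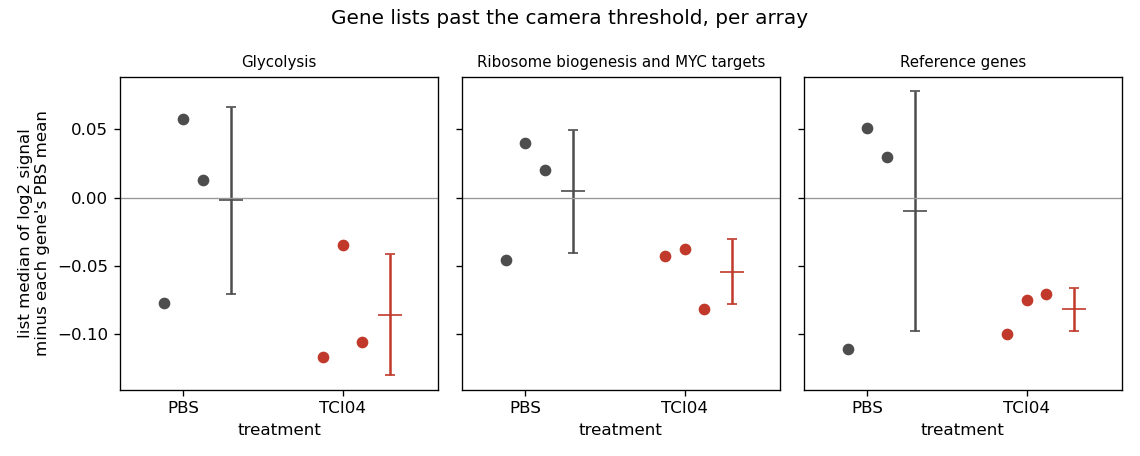
Median over the members of each list of the log2 signal minus each gene's mean in the PBS arrays (log2 units), for the 3 lists past the camera threshold. Points are arrays, and the bars beside them are the mean and SD of 3 arrays; PBS replicate 1, at -0.11 to -0.05, lay among or below the TCI04 arrays in each list.

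The next lists by camera p did not pass. The cytoskeleton list, with 15 of 23 members lower and an adjusted p of 0.188, had ACTB and the tubulin TUBA1B as its members with the highest level. TUBA1B had a log2 fold change of -0.09, and 0.036 after quantile normalization, and its other probe sets gave -0.167 to -0.143. In the heat shock list, 10 of 15 members had a lower mean (adjusted p = 0.236), with the chaperones HSP90AA1 at -0.17 and HSPD1 at -0.18, or -0.051 and -0.064 after quantile normalization. The other probe sets gave -0.08 to -0.031 for HSP90AA1 and -0.045 and -0.028 for HSPD1. In the list of ER chaperones and the unfolded protein response, 15 of 23 had a higher mean (adjusted p = 0.236), with HSPA5 at 0.07 and CANX at -0.02, which turned to 0.003 after quantile normalization.

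The lists of cell cycle genes did not pass. Of 39 measured members of DNA replication and G1/S, 27 had a higher mean, with a median of 0.03, and of 40 members of G2/M and mitosis, 24 did, with a median of 0.02 (camera, adjusted p = 0.703 and 0.546). The p53 targets had 13 of 22 and the apoptosis regulators 12 of 22 members with a higher mean (adjusted p = 0.546 and 0.754). The mesenchymal list, a state typical of this cell line, had 9 of 19 members with a higher mean, and matrix proteolysis and invasion 12 of 22 (adjusted p = 0.91 and 0.754). In none of these 6 lists did a member pass, over all genes or adjusted over the list alone. In cholesterol synthesis, 1 of 19 members passed adjusted over the list alone and not over all genes. It was the mevalonate kinase MVK, named after its value was seen, at 560 ± 66.4 with PBS and 400 ± 8.39 with TCI04, a log2 fold change of -0.47. This value is from the brightest of its 3 tested probe sets. The adjustment over a list alone was repeated in each of 35 lists, so chance can give such a pass.

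Luminal breast markers (11 measured) and fibroblast markers (5 measured) did not pass (camera, adjusted p = 0.999 and 0.754). Leukocyte and endothelial markers had 4 of 15 and 3 of 10 genes above the filter, too few to test.

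Of the 62 control probe sets, 22 were lower in every TCI04 array than in any PBS array, where chance gives 3.1, among them 4 for 18S or 28S ribosomal RNA. Several control probe sets measure the same transcript or spike, so they are not independent and the count spreads widely around 3.1. By RNA quality, 1 array stood apart. The 3' to 5' signal ratio of ACTB was 1.64 to 1.72 in the PBS arrays, 1.71 and 1.70 in TCI04 replicates 1 and 2, and 3.33 in TCI04 replicate 3 (exact two-sided permutation test between groups, p = 0.3, where 3 against 3 arrays cannot give less than 0.1). The ratio of GAPDH was 1.04 ± 0.0452 with PBS and 1.09 ± 0.118 with TCI04 (SD, n = 3, exact permutation p = 0.6). Without TCI04 replicate 3, the log2 fold change of FOS was -1.22 (limma, adjusted p = 0.00279) and 0 gene lists passed.

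The number of arrays limited the precision: the median 95% interval of a gene's log2 fold change reached 0.276 to each side, and for 86.2% of genes the whole interval lay within 2-fold.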

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

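The tests of replicate 3 for FOS and of the closer matching by level were chosen only after the results were seen, as was the median of the immediate-early genes with FOS, FOSB, DUSP1 and DUSP8 included.

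The 62 control probe sets were left out of the fit and of the list tests. Among them, the one for the 3' end of the spiked bacterial bioB control (AFFX-r2-Ec-bioB-3_at) was higher in all 3 TCI04 arrays than in any PBS array. Its log2 difference was 0.0905, with a lowest TCI04 signal of 1446 and a highest PBS signal of 1414. Chance gives 3.1 such control probe sets in each direction.

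The first pattern weighed is the lower FOS signal with TCI04. Without TCI04 replicate 3, the array with a low 5' signal, the log2 fold change was -1.22, and after quantile normalization it was -1.144 (adjusted p = 0.0138, with 0.00128 to 0.491 over all alternatives), which argues against that array or a level-dependent scaling difference as its source. The immediate-early genes without FOS, FOSB, DUSP1 and DUSP8, left out because their lower values had been seen, gave a median log2 fold change of 0.016 over 28 measured members, at the 62.58th percentile of random lists of like level; with those 4 genes, the median was 0.008 over 32, at percentile 49.03, and the 95% intervals of 27 of the 32 excluded a 1.5-fold fall. These intervals are those of each gene's probe set with the highest mean. For these probe sets they argue against a lowering of the whole class by 1.5-fold or more, by treatment or at harvest. They do not argue against one of a smaller set such as FOS, FOSB and DUSP8. The intervals of NR4A1 (-1.88 to 0.194) and CSRNP1 (-0.594 to 0.205) also allowed such a fall. Averaging probe sets, which gave lower values for some members such as EGR1 and FOSL2, was not part of this count. Of the 10 splits of the 6 arrays, 1, the real one, called a probe set, and the highest other count was 0; 10 splits are too few to give a share under 0.05. An effect of TCI04 on FOS, chance, and an untested difference in handling between the groups all stay open. The ribosomal RNA and thr control signals of the groups did not overlap either.

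The second pattern is the lower level of 3 gene lists. For ribosome biogenesis and MYC targets a trend with signal level is argued against. The list's median lay at percentile 0 of random lists matched in 20 bins and at percentile 0.01 with closer matching. Random lists are drawn gene by gene and leave out correlation between genes, so an extreme percentile is no evidence of an effect of TCI04. Lists that did not pass in camera were also extreme, with the cytoskeleton list at percentiles 0.01 and 0.02 and the ER chaperones at 99.31 and 99.22. For the reference genes the list's median lay at percentiles 5.47 and 39.57, so a trend among the brightest genes may account for the shift. For glycolysis the matchings part: the planned one gave percentile 0.27, at or below the 2.5th percentile set in advance as counting against a trend, and the closer one, added afterwards, gave 2.77, just above it. The planned matching left part of the trend in, since 8 of the 17 members lie in the brightest bin, whose 684 genes had a median of -0.02, and 3 of them among its 100 brightest genes, which had -0.11. Random lists had a median of 0.002 with the planned and -0.026 with the closer matching, against -0.069 for the list. After quantile normalization the glycolysis call was lost (camera, adjusted p = 0.137). Its members with the highest level, GAPDH and LDHA, then went from -0.135 and -0.133 to -0.035 and -0.021. How much of the shift a trend gave, and whether any lies beyond it, stays open, since the percentiles lie on both sides of the bound.

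The planned test of TCI04 replicate 3 as the source of the 3 list calls, their loss without that array (0 of 3 passed), came out as that source would predict, but leaving out PBS replicate 2 or PBS replicate 3 also left 0, while without PBS replicate 1 all 3 passed, so the part of this array cannot be told apart from that of PBS replicates 2 and 3. Of the 10 splits, 4 gave at least as many lists as the real one, which is among the 4 and gave 3. The highest other count was 7. Other splits thus gave as many lists, which was set in advance as the outcome if chance gave the calls. The number of lists called does not set the real split apart from regroupings of these arrays. A share under 0.05, which would have counted against chance, could not be reached with 10 splits. The splits with 4, 6 and 7 lists put PBS replicate 1 together with 2 TCI04 arrays, and called 1, 3 and 3 of these 3 lists, which points to a structure of the arrays in which PBS replicate 1 is low in these lists.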

How the results depend on the processing

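All alternatives were chosen before the data were examined, except that 13 of the 36 genes followed were picked after their values were seen. FOS kept its direction in all 19 alternatives and its call in 12, with adjusted p from 0.00128 to 0.491. The number of lower probe sets, and of genes lower by at least 2-fold, went from 1 to 0 in eBayes without trend and in the ordinary t-test, and ranged from 0 to 1 with single arrays left out; no setting gave a higher probe set. The number of gene lists went from 3 to 1 after quantile normalization and with the mean of a gene's probe sets, and to 0 with median centring, no filter, probe sets ending in _x_at or _s_at left out, eBayes without trend, an estimated correlation and fry; with single arrays left out it ranged from 0 to 6, the 6 without PBS replicate 1. Of the lists, ribosome biogenesis kept its call in 10 of 19 alternatives, and glycolysis and the reference genes in 7 each.

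Of the 36 genes, 29 kept their sign in every alternative that measured them, and none besides FOS passed in any. The other 7, all failing the correction, turned. Under quantile normalization CANX gave 0.003, TUBA1B 0.036 and JUN -0.005. With median centring CANX gave 0.036, DDX21 0.010 and EGR1 0.058. With the mean of probe sets N4BP2 gave -0.297, PHLDA1 -0.030 and JUN 0. With _x_at and _s_at probe sets left out JUN gave -0.020. With arrays left out PHLDA1 ranged from -0.020 to 0.088, EGR1 from -0.133 to 0.071, JUN from -0.019 to 0.050 and CANX from -0.043 to 0.001. The causes were not tested. The replicate numbers do not pair the arrays: same-numbered arrays deviated together with correlations of 0.004, 0.062 and 0.050, and the fit with the replicate block gave 1 lower and 0 higher probe sets, 1 gene lower by at least 2-fold and 4 lists, against 3 without it. Dim probe sets had the least precision, and FOSB and DUSP8 lay near the filter, where the offset sets the fold.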

Other observations

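The genes of this part were chosen after their values were seen, and none passed the correction over all genes. Beside FOS, 5 other immediate-early genes, FOSB, DUSP8, DUSP1, IER2 and FOSL2, had lower signals in all TCI04 arrays than in any PBS array, and 3 of the 32 measured, FOSL1, KLF10 and ZFP36, had higher signals in all. The AP-1 gene FOSB measured 86.1 ± 24.1 with PBS and 17.9 ± 11.3 with TCI04, a log2 fold change of -1.80, and the phosphatase gene DUSP8 measured 92.4 ± 20.6 and 29.0 ± 10.5, a log2 fold change of -1.38. Both are dim, so the offset sets the size: an offset of 1 gave -2.38 and -1.67, and the table median as offset gave -0.87 and -0.75. Each rests on 1 tested probe set. That of DUSP8 ends in _x_at, a type prone to cross-hybridization, so DUSP8 was not measured where such probe sets were left out. DUSP1 measured 5489 ± 229 and 4521 ± 119, a log2 fold change of -0.28, or -0.47 as the mean of its probe sets. IER2 had -0.18 and FOSL2 -0.08, or -0.37 as the mean of its probe sets. EGR1 had a log2 fold change of -0.002 with an interval from -0.24 to 0.24, and -0.22 as the mean of its 3 probe sets. JUN had 0.01 with an interval from -0.13 to 0.15, and FOSL1, another AP-1 gene, had 0.15, with 0.14 for KLF10 and for ZFP36. The limma adjusted p was 0.697 for FOSB, DUSP8, DUSP1, IER2, FOSL1 and KLF10, 0.747 for ZFP36, 0.771 for FOSL2, 0.998 for EGR1 and 0.981 for JUN.

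The list of ER chaperones and the unfolded protein response passed fry's mixed test for change in either direction (adjusted p = 0.0226), which does not compare it with other genes. In fry's test for a common direction the adjusted p was 0.699. None of its 23 measured members passed, over all genes or adjusted over the list alone. Its members with the smallest p differed in sign: the ER membrane protein WFS1 had a log2 fold change of -0.45, or -0.28 as the mean of its probe sets, and XBP1, a transcription factor of the unfolded protein response, 0.21. The list of ERK pathway output also passed the mixed test (adjusted p = 6.24e-05) and holds FOS.

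All 6 probe sets for the Bacillus thr control were lower in every TCI04 array, with log2 differences from -1.16 to -0.67, while the 3' probe sets for the dap, phe and lys controls overlapped between groups. The 5' signal of 18S ribosomal RNA was 12200 ± 1683 with PBS and 6591 ± 4209 with TCI04 (SD, n = 3, exact permutation p = 0.1, the smallest 3 against 3 can give), with 1744 in TCI04 replicate 3. In all, 22 of the 62 control probe sets, which are not independent of each other, lay lower in every TCI04 array, where chance gives 3.1 on average. Besides 6 for thr and 4 for ribosomal RNA, these included the 5' probe set of ACTB. Its signal was 20626, 21566 and 10981 in TCI04 replicates 1, 2 and 3, and 22439 to 23456 in the PBS arrays. By mean level, the median log2 fold change of genes ran from -0.16 in the dimmest of 10 bins of equal size to 0.04 in bin 9.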
